A study of Mus musculus with 2 samples.

How the data were processed

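H3K9me3 ChIP-seq peak lists were analysed for hearts of mouse embryos at 15.5 days, in 2 biological replicates that were separate pools of 78 and 62 embryos, with a library fragment size of 300 to 500 bp per the labels. The 2 samples form 1 group, so no contrast between groups was made and every p-value compares lists of positions, not conditions. The authors deposited 4 lists in narrowPeak format on mm10 (GRCm38), per the labels and the text files that describe the deposited data. The list of each replicate came from that replicate's filtered alignments and a control file of its own. The pooled list came from the alignments of both replicates and both control files. The replicated list was derived from both replicates' lists and the pooled list. The rule for keeping a peak in it, the aligner, the peak caller and their versions are not given in the sources used here.

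Each peak has a fold enrichment over the control, a linear ratio computed by the authors' peak caller. It also has a −log10 p and a −log10 q, both deposited by the authors, and a summit position. The lowest −log10 p in any list was just above 2, so the lists reach down to weak peaks. In the deposited lists 36.2% of the peaks of replicate 1, 19.4% of those of replicate 2, 50.0% of the pooled and 89.6% of the replicated peaks had a q of at most 0.05. These values belong to each list and were used to describe, rank or filter peaks within it. Fold and p depend on sequencing depth and on the control, and the deposited lists hold no read counts, so depth is unknown and the replicates' peak numbers cannot be set on a common depth.

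Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Genes came from GENCODE release M21 and sequence from the GRCm38.p6 assembly. Chromosomes 1 to 19, X and Y were used for every test. Peaks on unplaced and unlocalised scaffolds entered only counts per list, shares with a partner, rank correlations, overlaps between lists and the ranking of strongest peaks. Peaks were shared when they overlapped by at least 1 bp. A gene had a peak when a replicated peak overlapped its body or the 2000 bp upstream by at least 1 bp. Peaks were assigned by summit to promoter (1000 bp either side of a transcription start), 5' UTR, coding exon, 3' UTR, non-coding exon, intron or intergenic sequence, in that order. The body of each protein-coding gene was divided into 5 equal parts. Windows were 1 Mb wide, and domains joined peaks across gaps of up to 10000 bp.

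Chance was estimated by a permutation of positions, shifting all peaks of a chromosome by 1 random distance, at least 1 Mb and circular along its non-gap bases, which keeps the spacing of the peaks and of the genes. Replicate overlap, annotation and position along genes used 1000 shifts, gene lists 10000 and sequence content 100. Empirical p-values were two-sided, except for replicate overlap (one-sided). Their smallest possible values were 0.0002 for gene lists, 0.002 for two-sided tests with 1000 shifts, 0.001 for one-sided ones and 0.02 for 100 shifts. Benjamini-Hochberg adjustment ran over the 26 gene lists, the 7 annotation categories and the 5 parts of the gene body, with a threshold of 0.05. Numbers of peaks, chromosome shares, windows and domains were described without a test.

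The 26 gene lists covered zinc finger genes, 14 other gene families, 8 cell type or lineage lists, germ cell, imprinted and H3K9 methylation genes, taken by symbol. The lists, the tests, the rule for named genes and the alternatives were written before the data were examined, apart from those said to be added later. Named genes were the 3 genes of each list with the most covered bases and a peak in both replicates' own lists, the 10 protein-coding genes with the most covered bases, up to 10 cardiac genes with a replicated peak, the 5 peaks of highest fold and the 5 longest domains. Predicted genes named Gm with a number were passed over among the 10. Shares of small lists have Wilson intervals at 95%.

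Replicate overlap, gene lists, annotation and position along genes were tested on simulated data with known answers, and sequence content was computed on them. Windows, domains, sequence uniqueness and the later tests of explanations and of gene arrays were not run on simulated data. For replicate overlap, 2000 shared peaks planted among 22977 gave 2168 shared, with 241 by chance. For gene lists, peaks planted on 100 of 435 zinc finger genes gave a ratio of 2.90 (adjusted permutation p = 0.0052) and 0 of the other 25 lists passed. For annotation, 500 promoter peaks among 11814 gave a promoter ratio of 1.50 (adjusted permutation p = 0.014) and 0 of 6 other categories passed. For position along 422 genes, peaks planted at the 3' end put 68.4% of covered bases in the last part (adjusted permutation p = 0.0033). The planted promoter peaks also made 1 of the 5 parts of the 21516 other genes and the CpG ratio (1.19, permutation p = 0.02) pass, while GC (p = 0.24) and soft-masked content (p = 0.26) of the 11814 peaks did not.

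Alternatives were the pooled list, each replicate's list alone, the peaks above the median fold, a −log10 q of at least 2, autosomes only, stricter overlaps of at least 50%, other promoter, gene region, window and gap sizes, and random gene lists matched on gene length. Added after the data were seen were the replicated peaks found in both own lists and, for gene lists, peaks with a −log10 q of at least 2, with unique sequence, with low GC content or with few repeats. Sequence was called unique where at least 90% of the 50-base stretches of a peak occurred once in the assembly. By this measure 94.3% of the replicated peaks on chromosomes were of unique sequence, against 80.8% of the same peaks moved once along each chromosome. Shifted positions were not matched for uniqueness, so no ratio to shifted peaks is corrected for it.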

Results

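Trimethylation of lysine 9 of histone H3 (H3K9me3), a mark of silent chromatin, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in hearts of mouse embryos at 15.5 days of development. Both samples belonged to 1 group and were separate pools of hearts of the B6NCrl strain, 78 embryos in replicate 1 and 62 embryos in replicate 2, with male and female embryos together. Each pool had its own list of enriched regions (peaks), and both pools also contributed to a pooled list and to a shorter replicated list. The questions were where the mark lay in the embryonic heart, over which genes, and how far the separate pools gave the same map. The lists carried no read counts, so the depth of each library is unknown and no interval that needs it is given. All positions are on the mouse build mm10, counted from 1.

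The replicated list held 11448 peaks over 5287599 bp, and 2980 of 55413 annotated genes, among them 1858 of 21938 protein-coding genes, had a replicated peak in the gene body or the 2 kb upstream of it. Its peaks had a median width of 378 bp and a median fold enrichment over the control of 3.25, as the authors' peak caller gave it. They covered 0.193% of the non-gap bases of chromosomes 1 to 19, X and Y. Replicate 1 had 23284 peaks over 6300122 bp, with a median width of 227 bp and a median fold of 3.27. Replicate 2 had 44545 peaks over 11166090 bp, with a median width of 214 bp and a median fold of 3.02, so it listed 1.91 times as many peaks as replicate 1. The order turned among peaks with an authors' −log10 q of at least 2, of which replicate 1 had 2983 and replicate 2 had 2618. The pooled list held 56497 peaks over 16198748 bp with a median fold of 2.71.

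Strong peaks recurred in the other pool and weak ones mostly did not. Of the 100 peaks of replicate 1 with the highest authors' −log10 p, 99 (99%) overlapped a peak of replicate 2, and of the 100 strongest of replicate 2, 96 (96%) overlapped a peak of replicate 1. The shares were 73.0% and 68.7% for the strongest 1000 peaks and 26.7% and 20.2% for the strongest 20000. All these shares include peaks on scaffolds. Among genes of the fixed lists, the zinc finger gene Zfp981 had 28 peaks in replicate 1 and 35 in replicate 2, the imprinted gene Gnas 10 and 6, and the cardiac sodium channel gene Scn5a 2 and 2. Over whole lists, 5912 peaks of replicate 1 (25.4%) and 6014 of replicate 2 (13.5%) shared at least 1 bp with the other list. On the chromosomes 5668 of 22977 replicate 1 peaks had a partner, against 225 ± 25.1 (SD) when 1 list was shifted 1000 times along each chromosome, a ratio of 25.2 (one-sided permutation test, p = 0.001, the smallest it can give). Across the 5912 overlapping pairs, the fold of one replicate and that of the other had a Spearman rho of 0.169 and, on the log2 scale, a Pearson r of 0.24; peaks are not independent replicates and no p is given.

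**Figure D1:**
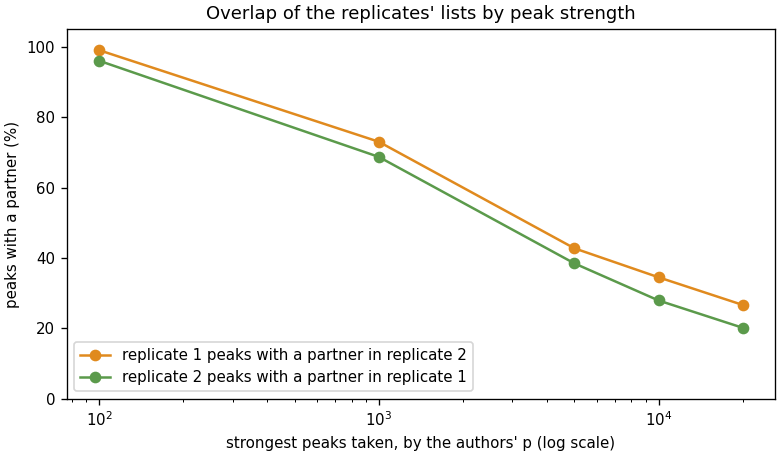
Share of each replicate's peaks with a partner in the other replicate (vertical axis, %) against the number of strongest peaks taken by the authors' p (horizontal axis, log scale), with 1 line per replicate. The share falls from 99% and 96% of the strongest 100 peaks to 26.7% and 20.2% of the strongest 20000.

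Of the 11448 replicated peaks, 7738 (67.6%) overlapped a peak of replicate 1's own list, 8889 (77.6%) one of replicate 2's, 5745 (50.2%) one of both and 566 (4.94%) one of neither. At Zfp981 the replicated list had 24 peaks and at Gnas 8. The germ cell gene Mael had a replicated peak of 418 bp with no peak in either replicate's own list. The cardiac channel genes Kcnq1, Scn5a and Cacna1c and the atrial light chain gene Myl4 had peaks in the replicated list and in both own lists. Replicated peaks that overlapped both lists had a median fold of 3.43, and the others 3.07. Every replicated peak was a pooled peak with identical position and values, so its fold is that of the pooled libraries.

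Genes of 5 of the 26 lists fixed beforehand carried replicated peaks more often than the same peaks shifted along the chromosomes. These were clustered protocadherins (47 of 58 genes, 81.0%), imprinted genes (30 of 51, 58.8%), zinc finger genes (137 of 435, 31.5%), vomeronasal receptors (101 of 565, 17.9%) and immunoglobulin variable segments (37 of 348, 10.6%). The 95% Wilson intervals of these shares were 69.1 to 89.1%, 45.2 to 71.2%, 27.3 to 36.0%, 14.9 to 21.2% and 7.81 to 14.3%, and cover counting error only. They treat genes as independent, although overlapping or neighbouring genes can share a peak, so they can be too narrow. All protein-coding genes together were below the shifted mean, with 1858 genes against 2245 ± 63.4 (SD), a ratio of 0.827. Each list was tested with 10000 circular shifts of the peaks along each chromosome, two-sided, with Benjamini-Hochberg adjustment over the 26 lists.

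**Figure D2:**
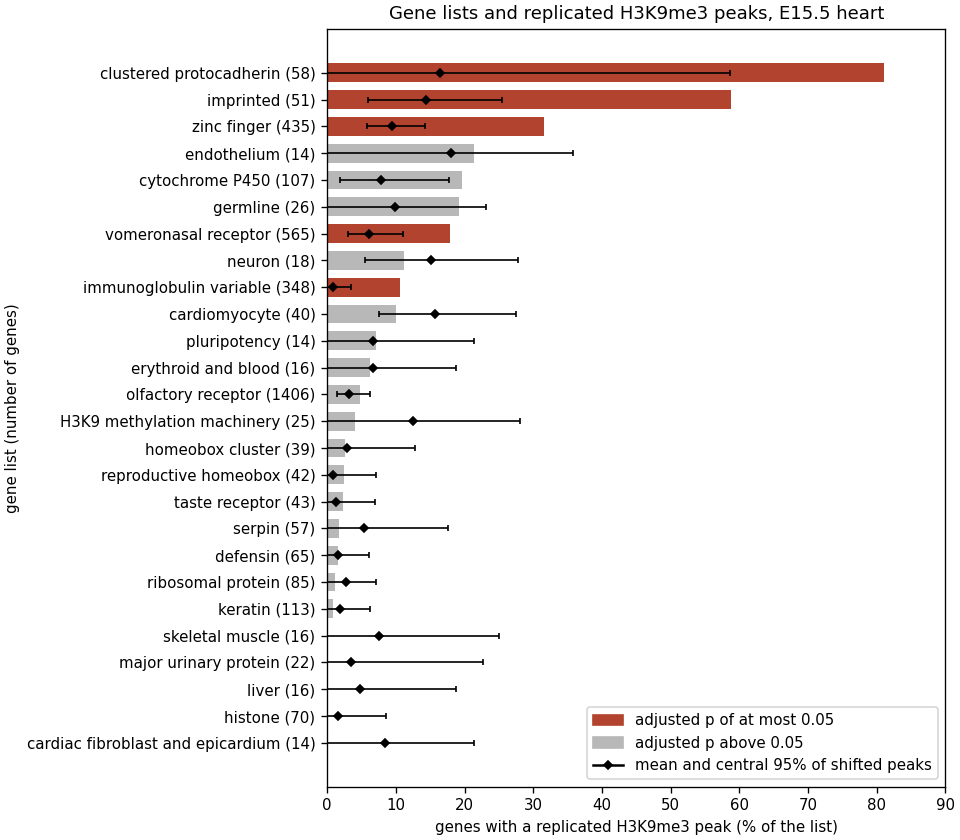
Share of the genes of each fixed list with a replicated H3K9me3 peak (bars, %), with the number of genes in parentheses; diamonds and whiskers give the mean and the central 95% of shifted peaks. The 5 red bars passed the adjusted permutation p of 0.05, from 10.6% of immunoglobulin variable segments to 81.0% of clustered protocadherins, and grey bars did not.

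Zinc finger genes, many of which encode DNA-binding repressors with a KRAB domain and lie in clusters, had 137 genes with a peak against 40.8 ± 9.41 (SD) in shifted lists, a ratio of 3.36 (permutation test, adjusted p = 0.0013). Zfp981 on chromosome 4 (146502027 to 146539395, plus strand) had 16784 bp under replicated peaks, 42.6% of its gene body and 2 kb upstream, with 15064 bp in replicate 1 and 13062 bp in replicate 2. Zfp936 on chromosome 7 (43114229 to 43192109) had 11694 bp in 26 peaks. Zfp110 (chromosome 7, 12834761 to 12850577), which encodes a factor that binds the neurotrophin receptor, had 10907 bp in 12 peaks, 61.2% of its region. The highest authors' fold was 5.95 at Zfp981, 4.69 at Zfp936 and 5.77 at Zfp110. The ratio was 2.03 with the list of replicate 1 alone, 1.57 with that of replicate 2 alone and 1.51 with the pooled list, each with an adjusted permutation p of at most 0.0013. Within 1 kb of the transcription start the excess was absent, with 6 genes against 6.06 ± 3.40 and an adjusted permutation p of 1.

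The mark lay toward the 3' end of zinc finger genes. In the 422 protein-coding zinc finger genes, the last of 5 equal parts of the gene body held 49.2% of all bases under replicated peaks and the first part held 2.38%. Shifted peaks gave 20.1% ± 7.18 (SD) and 20.1% ± 7.15, so the ratios were 2.45 and 0.118 (two-sided permutation test, adjusted p = 0.005 for each, from p = 0.002, the smallest that 1000 shifts can give). The last part held 47.2% with the list of replicate 1 and 45.3% with that of replicate 2. The last exon, which in these genes usually encodes the zinc finger array, had 13% of its bases under peaks against 2.72% of the other exons, a ratio of 4.79. In the 21516 other protein-coding genes the corresponding coverage was 0.310% and 0.238%. There the first 3 parts held 20.0, 21.1 and 19.9% of the covered bases, the next part 16.4% (ratio 0.824, adjusted permutation p = 0.01) and the last 22.5% (ratio 1.13, adjusted p = 0.13). The lower share in the part before the last did not pass with the list of replicate 1 alone (ratio 0.919, adjusted permutation p = 0.24) or with the peaks above the median fold (0.846, adjusted p = 0.16).

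**Figure D3:**
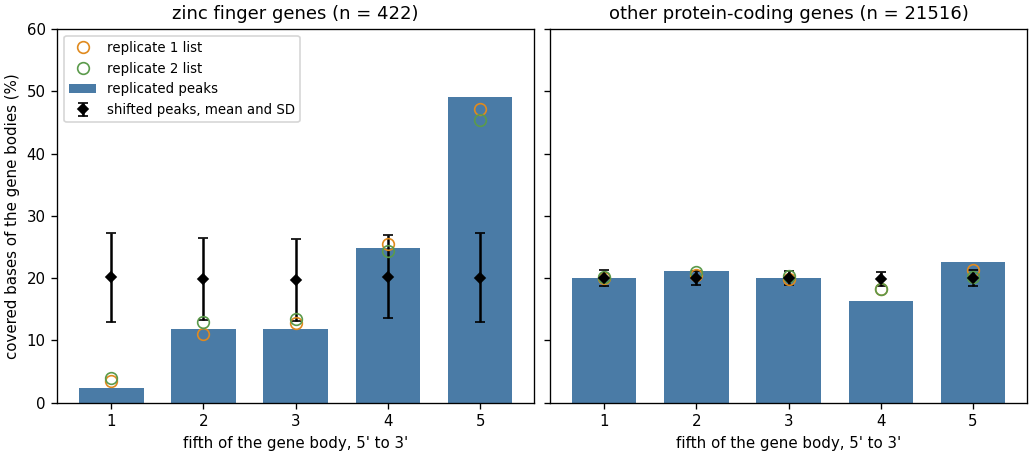
Share of the bases under peaks in each of 5 equal parts of the gene body from 5' to 3' (bars, %), for 422 zinc finger genes on the left and 21516 other protein-coding genes on the right; circles are the replicates' own lists, and diamonds with whiskers are the mean and SD of shifted peaks. The last part of zinc finger genes holds 49.2% with replicated peaks, 47.2% with replicate 1 and 45.3% with replicate 2.

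**Figure D4:**
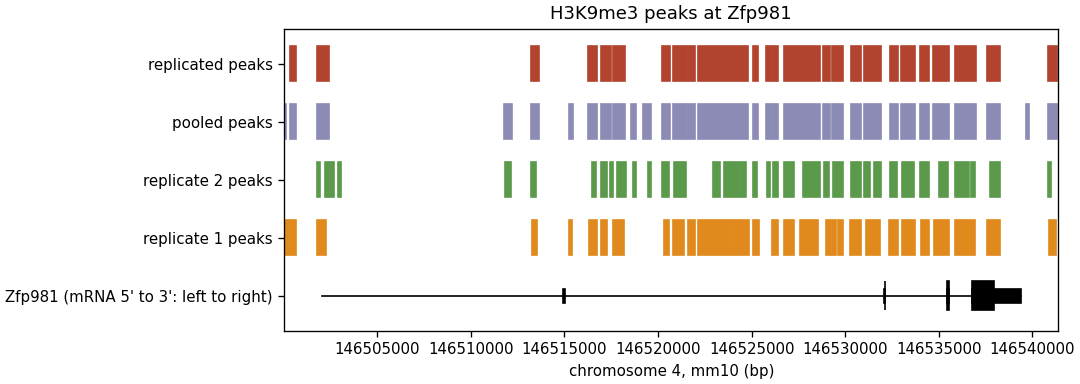
Peaks of the replicated, pooled, replicate 2 and replicate 1 lists at Zfp981 on chromosome 4 (horizontal axis, position in bp on mm10), above the gene model with exons as boxes and the coding part thicker. Most of the 24 replicated peaks of the gene lie between 146520210 and 146538267, and most of their bases are in introns of the drawn model. Exon 1 and exon 2 have no replicated peak, exon 3 lies under one, and exon 4, the last, is covered in part. Most covered bases lie upstream of this last exon.

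Clustered protocadherins, vomeronasal receptors and immunoglobulin variable segments carried the mark as well. Clustered protocadherins, cell adhesion proteins of neurons encoded in a row on chromosome 18, had 47 genes with a peak against 9.56 ± 9.92 (SD), a ratio of 4.91 (permutation test, adjusted p = 0.0013). Pcdhga1, Pcdhga2 and Pcdhga3 had 19349, 18423 and 17287 bp under replicated peaks, but their gene models share a 3' end and most of these bases are counted in each. Within 1 kb of a transcription start, where the models are separate, 22 of the 58 genes had a peak against 0.371 ± 0.702, a ratio of 59.3 (adjusted permutation p = 0.00173). Vomeronasal receptors, which detect pheromones, had a ratio of 2.91 (34.7 ± 11.4 expected, adjusted permutation p = 0.0013), led by Vmn2r-ps54 with 4887 bp, Vmn2r60 with 3988 bp and Vmn2r59 with 3123 bp, all on chromosome 7. Their excess did not pass the test within 1 kb of the start (25 genes, ratio 2.57, adjusted permutation p = 0.146) or when at least 10% of the gene body had to be covered (13 genes, ratio 2.74, adjusted p = 0.39). Immunoglobulin variable segments, the units that lymphocytes recombine, had a ratio of 12.1 (3.05 ± 3.01 expected, adjusted permutation p = 0.00208). Ighv1-70, Ighv1-25 and Ighv1-65 on chromosome 12, each annotated as a pseudogene, had 1059, 1038 and 966 bp under peaks, 43.5, 42.8 and 39.8% of their regions. The median length in this list was 463 bp, so most of each tested region is the 2 kb upstream and not the segment. With the lists of replicate 1 and replicate 2 alone the ratios were 2.54 and 1.84 for protocadherins, 2.27 and 1.70 for vomeronasal receptors and 7.95 and 5.48 for immunoglobulin segments, all past the threshold. With the peaks at or below the GC content of the genome, protocadherins did not pass (33 genes, ratio 9.33, adjusted permutation p = 0.0637).

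Imprinted genes, expressed mainly from the allele of one parent, had 30 genes with a peak against 7.33 ± 2.74 (SD), a ratio of 4.09 (permutation test, adjusted p = 0.0013). Gnas, which encodes the stimulatory G protein alpha subunit, had 4061 bp under 8 replicated peaks. Mest, a paternally expressed hydrolase gene, had 2985 bp and Blcap 2398 bp. The same 2398 bp fell on Nnat, which lies inside Blcap. Kcnq1 and the antisense transcript Kcnq1ot1 both had 1910 bp in 5 peaks, so all replicated peaks of this potassium channel gene lay over Kcnq1ot1 or the 2 kb upstream of it. The ratio was 2.83 with the list of replicate 1 alone and 1.82 with that of replicate 2 alone. Peaks on these genes had a median GC content of 54.3% against 44.0% for all replicated peaks, and with peaks at or below the GC content of the genome the ratio was 1.29 (adjusted permutation p = 1).

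Genes of heart muscle were not marked more often than shifted peaks gave. Of 40 cardiomyocyte genes, 4 (10%, Wilson interval 3.96 to 23.1%) had a replicated peak against 6.29 ± 2.04 (SD), a ratio of 0.636 (permutation test, adjusted p = 0.945). Kcnq1 had 1910 bp, Scn5a (chromosome 9, 119483408 to 119579016) 474 bp, Cacna1c, the L-type calcium channel, 314 bp and Myl4 271 bp, and none of the 40 had a peak within 1 kb of its start. None of the 14 cardiac fibroblast and epicardium genes had a replicated peak, with 0 in replicate 1 and 2 in replicate 2. Of 14 endothelial genes 3 had one, the receptor genes Tek (653 bp), Flt1 (640 bp) and Npr3 (456 bp). Of 16 erythroid and blood genes 1 had one, the macrophage gene Adgre1 (1126 bp). The adjusted permutation p of these 3 lists was 1.

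Lists of genes of other lineages did not pass the test over gene bodies with the replicated list. Of 18 neuronal genes 2 had a replicated peak, Slc17a7, a vesicular glutamate transporter (2149 bp), and the synaptic gene Snap25 (370 bp). The 16 skeletal muscle and the 16 liver genes had none, with 3 and 1 of them in replicate 1 and 2 and 0 in replicate 2. The only pluripotency gene of 14 was Esrrb (312 bp), and the only one of 25 genes of the H3K9 methylation machinery was Atf7ip (1292 bp), a partner of the methyltransferase Setdb1. All these lists had an adjusted permutation p of at least 0.924. Of 26 germ cell genes, 5 had a replicated peak (ratio 1.96, adjusted permutation p = 0.743; with the peaks soft-masked over at most 10%, an alternative added later, 4 genes, ratio 5.98, adjusted p = 0.0355; with the lists of replicate 1 and replicate 2 alone, ratios 0.754 and 1.33, not passing), with 931 bp at Dazl, 888 bp at Taf7l and 426 bp at Tex11. All 5 also had one within 1 kb of the transcription start, where shifted peaks gave 0.243 ± 0.492 genes, a ratio of 20.6 (adjusted permutation p = 0.00173). Only at Dazl and Taf7l did a start peak overlap peaks of both own lists, and at Mael it overlapped neither. The start peaks of the 5 genes had a GC content of 53.8 to 71.2%, and with the peaks at or below the GC content of the genome none of the 26 genes had one. Ddx4, Mael, Esrrb and Rpl3 are named here because their lists had 5 or fewer such genes, after their values were seen; Ddx4 had 710 bp and Mael 418 bp.

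Among the remaining families, 67 of 1406 olfactory receptor genes had a replicated peak (ratio 1.48, adjusted permutation p = 0.845), led by Olfr398 (1857 bp), Olfr1349 (1127 bp) and Olfr870 (1066 bp). With the lists of replicate 1 and replicate 2 alone this list passed, with 155 and 292 genes and ratios of 1.86 and 1.98 (adjusted permutation p = 0.0295 and 0.00173). It also passed with the pooled list (326 genes, ratio 1.94, adjusted permutation p = 0.00173) and against random lists matched for gene length (ratio 1.56, adjusted p = 7.43e-04). Cytochromes P450, enzymes of drug and steroid metabolism, had 21 of 107 genes with a peak (ratio 2.49, adjusted permutation p = 0.13), led by Cyp2c29 (3483 bp), Cyp3a11 (1917 bp) and Cyp3a63-ps (1655 bp). They passed with the list of replicate 2 (ratio 1.71, adjusted permutation p = 0.0409) and not with that of replicate 1 (1.90, adjusted p = 0.0966). They also passed with the pooled list (ratio 1.70, adjusted permutation p = 0.028), with random lists matched for gene length (3.0, adjusted p = 7.43e-04) and with the peaks in both own lists, an alternative added later (3.55, adjusted p = 0.0477). Random lists do not keep the clustering of gene families and peaks, so their p-values treat clustered genes as independent. For olfactory receptors their SD was 6.20 genes against 17.6 with shifted peaks. Single genes had peaks among 39 Hox genes (Hoxd11, 317 bp), 65 defensins (Defb39, 406 bp), 57 serpins (Serpinb6d, 820 bp), 43 taste receptors (Tas2r107, 189 bp), 42 reproductive homeobox genes (Rhox13, 966 bp), 113 keratins (Krt8-ps, 261 bp) and 85 ribosomal proteins (Rpl3, 305 bp). None of 70 histone genes and none of 22 major urinary protein genes had a replicated peak or a peak in either replicate's own list. The adjusted permutation p of these 9 lists was at least 0.945. With the pooled list ribosomal protein genes passed as depleted (2 of 85, ratio 0.221, adjusted permutation p = 0.028).

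Relative to gene structure, replicated peaks lay more often between genes and in coding exons, and less often in introns, than shifted peaks. By summit, 58.7% were intergenic against 49.9% ± 1.64 (SD), 2.19% were in coding exons against 1.04% ± 0.124, and 28.4% were in introns against 39.9% ± 1.48. The ratios were 1.18, 2.10 and 0.712 (two-sided permutation test, adjusted p = 0.00467 for each over 7 categories). Promoters, within 1 kb of a transcription start, held 7.64% against 6.65% (ratio 1.15, adjusted permutation p = 0.0532), and peaks at the starts of Dazl, Peg3 and Nnat fell in this category. Shares in non-coding exons (ratio 1.24, adjusted permutation p = 0.0532), 3' UTRs (1.23, adjusted p = 0.077) and 5' UTRs (1.14, adjusted p = 0.86) did not pass. With the peaks in both own lists non-coding exons (1.48, adjusted permutation p = 0.0084) and 3' UTRs (1.36, adjusted p = 0.0303) passed as enriched. With the list of replicate 2 alone 3' UTRs passed as lower (0.864, adjusted permutation p = 0.0336). The coding exon ratio was 1.57 with the list of replicate 1, 1.22 with that of replicate 2 and 3.22 by covered bases, and the excess was lost with the pooled list (ratio 1.11, adjusted permutation p = 0.118). The promoter ratio turned to 0.824 with the pooled list (adjusted permutation p = 0.00467). It was 0.838 with the list of replicate 2 alone (adjusted permutation p = 0.0035) and 0.933 with that of replicate 1. Promoters passed as enriched with the peaks in both own lists (1.301, adjusted permutation p = 0.0035) and by covered bases (1.284, adjusted p = 0.0233).

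Sequence under the replicated peaks was richer in G and C than shifted positions, at 44.6% against 42.1% ± 0.243 (SD), a ratio of 1.06 (two-sided permutation test, p = 0.02, the smallest that 100 shifts can give). Median GC content was 41.5% in peaks on zinc finger genes, 43.2% on vomeronasal receptors, 46.3% on clustered protocadherins and 54.3% on imprinted genes. The ratio of observed to expected CpG was 0.181 in peaks against 0.194 ± 0.00343 (permutation p = 0.02). It turned, without passing the test, with the peaks above the median fold (ratio to shifted 1.01, permutation p = 0.44) and with the peaks in both own lists (1.02, p = 0.24). Soft-masked repeats made up 33.1% of the covered bases against 33.8% ± 0.673 (permutation p = 0.3). On protocadherin and imprinted genes the median peak was soft-masked over 6.62 and 7.51% of its length, and on vomeronasal receptors over 34.3%.

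Chromosomes 7, 17 and 4 held the densest coverage. Chromosome 7, with the imprinted genes Peg3, Kcnq1ot1 and Snrpn and clusters of zinc finger and vomeronasal receptor genes, had 1769 replicated peaks over 808182 bp, 0.570% of its non-gap bases. That was 15.8% of all covered bases, 2.95 times the chromosome's share of the genome. Chromosome 17 was at 2.28 times its share, chromosome 4 at 1.58 and chromosome 5 at 1.26. The lowest were chromosome 14 at 0.492, chromosome X at 0.282 with 197 peaks and chromosome Y at 0.0273 with 10 peaks. For chromosome 7 the value was 2.45 with the list of replicate 1 and 2.18 with that of replicate 2. For chromosome X it was 0.447 and 0.552, over 1.5 times the replicated value, and for chromosome Y 0.0187 and 0.0174, the latter less than the replicated value by over 1.5 times. The Y chromosome is 96.3% soft-masked and chromosome X 46.8%, and pools of male and female embryos hold fewer copies of both than of the autosomes.

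**Figure D5:**
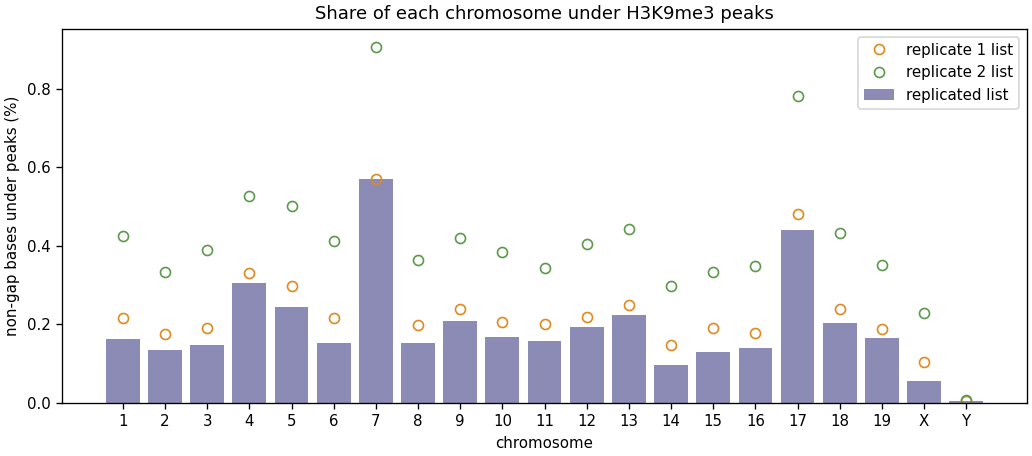
Share of the non-gap bases of each chromosome under peaks (vertical axis, %), with bars for the replicated list and circles for the replicates' own lists. Chromosome 7 is highest in the replicated list at 0.570% and in both replicates' lists, followed by chromosome 17.

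Covered bases were unevenly spread along the chromosomes. Of 2737 windows of 1 Mb, 2102 had a replicated peak, and the 25 densest held 20.6% of all covered bases. The densest in the replicated list, chromosome 7 from 33000001 to 34000000, had 60559 bp under peaks and holds secretoglobin genes (Scgb1b and Scgb2b). It had rank 2 in both own lists. First there were chromosome 4 from 147000001 to 148000000 in replicate 1 (51190 bp) and chromosome 18 from 37000001 to 38000000 in replicate 2 (67301 bp). Chromosome 7 from 17000001 to 18000000 had 60183 bp and holds genes of the Ceacam and Psg cell surface and placental glycoprotein families. In it Ceacam5 had 7131 bp and Psg29 754 bp under replicated peaks, both named after their values were seen. Chromosome 4 from 147000001 to 148000000 had 59587 bp and 10 zinc finger genes, and chromosome 18 from 37000001 to 38000000 had 56074 bp and all 58 clustered protocadherins. The window on chromosome 7 from 12000001 to 13000000 (51007 bp) held 9 zinc finger and 22 vomeronasal receptor genes. The window on chromosome 1 from 88000001 to 89000000 (48975 bp) held Mroh2a and the Ugt1a glucuronosyltransferases. Windows with at least 3 zinc finger genes were 45 (1.64%) of all windows and held 13.4% of the covered bases (9.81% with the list of replicate 1 and 7.26% with that of replicate 2), and 7 of the 25 densest were among them. The 25 densest windows held 14.4% of the covered bases of replicate 1 and 11.3% of those of replicate 2.

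Over single protein-coding genes, Mroh2a on chromosome 1 (88226986 to 88262289), a gene of the maestro heat-like repeat family, had the most covered bases in the replicated list. It had 22794 bp in 16 replicated peaks or 61.1% of its region, with 17591 bp in replicate 1 and 19213 bp in replicate 2. Skint5 and Skint6 on chromosome 4, relatives of a gene needed for skin T cell development, had 18759 bp in 47 peaks and 16443 bp in 44 peaks. In both own lists Skint5 had more covered bases than Mroh2a, 18374 bp in replicate 1 and 26350 bp in replicate 2. Skint6 had 16604 and 28620 bp there. Zfp981 and the protocadherin genes Pcdhga1, Pcdhga2, Pcdhga3, Pcdhgb1 (17287 bp), Pcdhga4 (17076 bp) and Pcdhgb2 (16247 bp) completed the first 10, after 3 predicted genes named Gm with a number were passed over.

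When peaks up to 10 kb apart were joined, the replicated list gave 6965 domains, of which 706 held at least 3 peaks and 21 were at least 50000 bp long. The longest ran from 17909354 to 18022848 on chromosome 7 (113495 bp, 39 peaks), over Ceacam11 and Ceacam13. The next lay on chromosome 4 from 112669093 to 112767429 (98337 bp) over Skint10, on chromosome 7 from 33652738 to 33747785 (95048 bp) over Scgb1b24 and Scgb2b24, and on chromosome 17 from 39021733 to 39113460 (91728 bp) spanning the pheromone genes Esp22, Esp23 and Esp24, none of which had a replicated peak in its body or the 2 kb upstream. The last of the longest 5, on chromosome 4 from 121975106 to 122059839 (84734 bp), had 48 peaks and no protein-coding gene. Domains of at least 3 peaks numbered 1301 with the list of replicate 1 and 2758 with that of replicate 2, and those of at least 50000 bp 50 and 107. The longest domains depend on the joining distance: with gaps of up to 5 kb, 2 reached 50000 bp and the longest had 56989 bp, and with gaps of up to 20 kb, 106 did and the longest had 523670 bp.

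The strongest single peak by the authors' deposited fold lay on chromosome Y from 259010 to 259542, with a fold of 12.2 in the replicated list, 15.2 in replicate 1 and 9.18 in replicate 2, and 51222 bp from the nearest annotated gene. The next was on chromosome 13 from 119488148 to 119489293, inside 3110070M22Rik (deposited fold 8.52, with 6.65 in replicate 1 and 3.47 in replicate 2). It was followed by a peak on the unplaced scaffold Un_GL456383 from 2884 to 4873 (8.50, with 3.94 in replicate 1 and 7.86 in replicate 2). A peak of 1914 bp on chromosome 2 (180642574 to 180644487) lay in Tcfl5, a transcription factor gene of the testis, with a deposited fold of 8.48. A peak of 2522 bp on chromosome 6 (30956413 to 30958934) lay over Klf14, an intronless imprinted transcription factor gene, with a deposited fold of 8.02. The highest folds in replicate 1 and replicate 2 were 7.33 and 7.55 at the Tcfl5 peak and 6.57 and 6.22 at the Klf14 peak. All 5 overlapped peaks of both replicates' own lists.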

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

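The tests in this part were chosen after the patterns had been seen in the lists, and were set down before their own results were seen. Only 1 group was measured, so no biological explanation was tested. Peaks on unplaced and unlocalised scaffolds, which no comparison with genes or shifted peaks used, numbered 234 in the replicated list (2.04%) over 182520 bp, with 200 of them (85.5%) in both replicates' own lists against 49.4% of peaks on chromosomes. The largest number, 63, lay on Un_JH584304.

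Zinc finger genes carried replicated peaks 3.36 times as often as shifted lists gave, and reads shared between near-identical copies, GC content or interspersed repeats could each raise such a count. With the 10572 peaks of unique sequence the ratio was 3.33 (133 genes, permutation test, p = 0.0002, the smallest it can give). With the 3673 peaks at or below the GC content of the genome it was 4.97, and with the 2549 peaks that were soft-masked over at most 10% it was 5.19, both at the same smallest p. The first value argues against exactly repeated sequence as the whole cause. The filtered peaks were shifted to positions not matched for GC content or repeats, so 4.97 and 5.19 cannot be compared with 3.36. In counts, 84 zinc finger genes had a peak of low GC content and 67 one with few repeats. All replicated peaks, shifted without a filter, gave 40.8 ± 9.41 (SD). These counts argue against high GC content or repeats within the peaks, each as the whole cause. Repeats beside the peaks were not tested. Copies with small differences in sequence can count as unique, so reads shared between such near-identical copies stay open. A biological origin, such as the KRAB zinc finger proteins acting on their own gene clusters, stays a hypothesis that these lists do not test.

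The excess in vomeronasal receptors, clustered protocadherins and immunoglobulin variable segments could also come from reads shared between near-identical members of these tandem families. With peaks of unique sequence the ratios were 2.92, 5.06 and 12.3 (permutation test, p = 0.0002, 0.0002 and 0.0004). These values argue against reads from exactly repeated sequence as the whole cause in all 3 families. Copies with small differences in sequence can count as unique, so reads shared between such near-identical copies stay open. Of the peaks on these families, 96.5, 100 and 95.8% were of unique sequence, against 86.1% on zinc finger genes. Differences between the B6NCrl strain and the reference in the copy number of such families stay open.

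Replicate 2 listed 1.91 times as many peaks as replicate 1, which could come from background calls spread evenly over the genome. Of its 38448 peaks without a partner, 14716 (38.3%) lay within 10 kb of a replicate 1 peak, against 12.8% ± 0.461 (SD) for shifted positions, a ratio of 2.99 (one-sided permutation test, p = 0.001, the smallest it can give). Even spread is therefore not the whole cause. A difference in depth or in the control stays open, because the lists give neither.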

How the results depend on the processing

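Tests with the replicated peaks found in both own lists and, for gene lists, with peaks of high −log10 q, unique sequence, low GC content or few repeats were chosen after the data were seen; the other tests here were planned. Of 701 values under an alternative, 553 kept their direction and side of the threshold or, without a test, stayed within their spread, 1.5 times (counts, lengths, peak number and exon ratios) or 0.05 (rank correlation), 7 no longer passed, 23 newly passed, 7 reversed and 111 moved. The 5 lists that passed did so in 64 of 69 values, and other lists in 11 of 293. Covered bases of named genes stayed within 1.5 times in 77 of 141 values. Depth is unknown, so its effect on any value could not be measured. No paired analysis was possible because there is only 1 group.

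Fewer peaks by construction gave 5724 replicated peaks above the median fold and 7453 with a −log10 q of at least 2, and 2280 and 711 shared replicate 1 peaks. Of these shared peaks, 2210 and 573 lay on chromosomes and the others on scaffolds. A reciprocal overlap of 50% gave 3015 shared peaks and a Spearman rho of 0.242; −log10 p in place of fold gave 0.240. The peak number of replicate 2 over replicate 1 reversed to 0.878 at a −log10 q of at least 2.

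Annotation categories past the threshold, 3 in the replicated list, were 5 above the median fold, 7 by covered bases, 6 with peaks in both own lists and 3 to 5 without one replicate. Without one replicate the 3' UTR ratio was 0.864 to 1.03 and the promoter ratio 0.838 to 0.933. Both were lowest without replicate 1, where they reversed. With the pooled list the promoter ratio reversed to 0.824, while promoters passed as enriched by covered bases and with peaks in both own lists. Gene lists past the threshold were 8 with the pooled list and 3 with peaks of low GC content. Within 1 kb of the start the zinc finger ratio was 0.991 and the vomeronasal ratio 2.57; with at least 10% of the gene covered the vomeronasal ratio was 2.74. With peaks of low GC content the protocadherin ratio was 9.33 (adjusted permutation p = 0.0637) and the imprinted ratio 1.29. The CpG ratio reversed to 1.01 above the median fold and to 1.02 with peaks in both own lists. The soft-masked ratio was 0.973 to 0.975 without one replicate, and passed without replicate 1.

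Chromosome 7 held 2.48 times its share with the pooled list and 2.18 to 2.45 without one replicate. The 25 densest windows held 13.8% with the pooled list, 11.3 to 14.4% without one replicate, 23.3% with peaks in both own lists and 24.6% with windows of 500 kb, which are more numerous. Domains of at least 3 peaks numbered 3939 with the pooled list, 1301 to 2758 without one replicate, 326 above the median fold and 301 with peaks in both own lists. Except where fewer or more peaks entered by construction, the cause was not tested.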

Other observations

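The test of gene arrays in this part was set down before its result was seen, and the genes were chosen after the lists had been seen. At transcription starts of imprinted genes, 13 of 51 genes had a replicated peak within 1 kb, against 0.765 ± 0.997 (SD) for shifted peaks, a ratio of 17 (permutation test, adjusted p = 0.00173). The start peaks of these 13 genes had a GC content of 43.8 to 64.1%, all above the 41.7% of the non-gap genome. Shifted positions were not matched for GC content. Nnat, a brain proteolipid gene, had a peak of 1430 bp (chromosome 2, 157559108 to 157560537) with an authors' fold of 3.57. A peak of 864 bp on chromosome 7 (6729908 to 6730771, fold 4.33) lay at the start shared by Peg3 and Usp29, and one of 450 bp on chromosome 6 (4747761 to 4748210, fold 4.15) at that of the retrotransposon-derived Peg10 and its neighbour Sgce. Kcnq1ot1 had one of 343 bp at its start on chromosome 7 (143295524 to 143295866), and the non-coding gene Meg3 one of 647 bp on chromosome 12 (109539897 to 109540543, fold 2.43). All of these overlapped peaks of both replicates' own lists. The start peaks of Snurf (540 and 530 bp) and Mkrn3 (341 bp) each overlapped a peak of only 1 own list, and further ones at Peg3 and Usp29 (406 bp) and Gnas (264 bp) overlapped none. At germ cell genes, Dazl, an RNA-binding protein gene, had a peak of 931 bp at its start on chromosome 17 (50293211 to 50294141, fold 4.45) with a GC content of 61.1%, present in both replicates. Ddx4, a germ cell helicase gene, had one of 710 bp on chromosome 13 (112651818 to 112652527) with a peak in replicate 2 alone.

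Pseudogenes, taken with the 2 kb upstream of them, had replicated peaks more often than shifted peaks gave. Among processed pseudogenes 240 of 9940 had a replicated peak (ratio 1.99, p = 0.0002, the smallest of this permutation test), and among unprocessed ones 120 of 2642 (ratio 2.18, p = 0.0004), without adjustment. Their median lengths were 552 and 917 bp, so most of each tested region is upstream sequence. Members of the fixed lists were not taken out, and sequence uniqueness was not checked for these sets. Long intergenic RNA genes were at 342 of 5854 (ratio 1.04, permutation p = 0.45).

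The families named here, outside the fixed lists, were chosen after their values were seen, and no difference between families was tested. All 8 Skint genes and all 5 Ceacam genes counted in tandem arrays had a replicated peak, as did 6 of 7 sulfotransferase (Sult) genes, 10 of 19 Ugt genes, 11 of 29 secretoglobin (Scgb) genes and 5 of 10 killer cell lectin-like receptor (Klra) genes. Such counts can take 1 peak for several overlapping genes. Added gene by gene, the Ugt genes had 62588 covered bp, more than the 48975 bp of the whole chromosome 1 window with the Ugt1a genes. Peaks may therefore be counted in more than 1 Ugt gene. None had a replicated peak among 26 Klk, 22 Prl, 21 Lce, 19 Ces, 11 Psg and 11 Esp genes counted in arrays, though in the own lists of replicate 1 and replicate 2 Klk and Prl had 1 and 3 genes each, Lce 0 and 1, Ces 0 and 4, Psg 3 and 5, and Esp 1 and 5. Psg29, which had bases under replicated peaks, was not among the 11 Psg genes counted. The hypothesis that genes in tandem arrays carry the mark more often in general was tested on genes outside the fixed lists with at least 5 members of the same family, by symbol, within 500 kb either side. Over all 773 such genes, 77 had a peak (ratio 1.81, permutation p = 0.001), but these include the windows that prompted the hypothesis. They also include the Ugt genes, which may share peaks. Among the 729 genes outside the 25 densest windows, 53 had a peak (7.27%), a ratio of 1.40 (two-sided permutation test, p = 0.096), and the ratio was 1.09 with the list of replicate 1 and 1.14 with that of replicate 2. These ratios are biased downward, because the shifted peaks include those of the 25 densest windows while the 729 genes lie outside these windows. Of the 18405 protein-coding genes outside arrays and fixed lists, 1406 had a peak (7.64%), a ratio of 0.689 (permutation p = 0.0002). The mark may therefore be common to tandem arrays or belong to a few families, and these lists leave that undecided.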
